A study of Mus musculus with 108 samples.

How the data were processed

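The samples were brain, heart, kidney, liver, lung and testis of male mice of 6 inbred strains, C57BL/6J, A/J, DBA2/J, 129S2, C3HeB/FeJ and AKR/J, at 11 to 14 weeks of age, per the labels. Strain, tissue and animal number were taken from the sample titles, which give 3 animals for each of the 36 combinations of strain and tissue, 108 arrays and 22 animals in all. The same animals served all 6 tissues in A/J, DBA2/J, C3HeB/FeJ and AKR/J. In C57BL/6J, animals 2, 3 and 4 gave brain, heart and lung and animals 10, 11 and 12 gave kidney, liver and testis. In 129S2, animals 1, 2 and 3 gave the first set of tissues and animals 2, 3 and 4 the other. For 4 arrays the number in the title differs from that in the source name, and the title was used. Of these, 3 are the 129S2 brain arrays, whose numbers 1, 2 and 3 in the titles are 3, 1 and 2 in the source names. The other is kidney array 129S2 4, whose source name gives animal 3. By source name 2 of the 129S2 kidney arrays would thus come from 1 animal. The labels' protocol text speaks of pools although the titles name single animals, so the arrays were treated as separate animals as the titles have it. Males only were measured, and the labels give no scan dates or batches.

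The values are log2 signals of Affymetrix probe sets, which the authors deposited after RMA (background correction, quantile normalization and summarisation of probes), per the submitters' processing notes, with no version stated. Each array was a column of the deposited table, all columns were used, and no value was changed before testing. Within a tissue the distributions of the 18 arrays were near identical and between tissues they differed, as when each tissue is normalized by itself. Whether the tissues were normalized together is not given in the sources used here. Fits were therefore made within a tissue, or on contrasts between strains taken within tissues. Replicate arrays were compared before averaging. The highest share of identical values between 2 replicates was 0.166% of probe sets, so no array was counted as a copy of another.

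Of 45101 probe sets, 64 control probe sets were left out, 13 of which the probe table assigns to a gene. A further 932 probe sets with several genes and 9211 with no listed gene were left out. The 34958 probe sets with a single gene were used, and 34754 of them matched the GRCm38.p6 gene table by gene ID. That table was used only for names and for which genes are neighbours, and no coordinates are printed because the genome build behind the probe design is not given in the sources used here. Each of the 18193 genes tested took the value of its probe set with the highest mean log2 over all arrays. For the 9010 genes with 2 or more probe sets, the number of probe sets with a passing difference of the same and of the opposite sign was counted. A gene's value is relative hybridisation signal, so sequence differences between strains under a probe can change it without a change in transcript level.

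Tests were run in R 4.3.3 with limma 3.58.1. Per tissue, a linear model with 1 mean per strain was fitted and the 6 strains were compared with the moderated F test (default prior), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. For strain against C57BL/6J, all 108 arrays were fitted with 1 mean per combination of strain and tissue, the animal as a random block (consensus correlation 0.0174, estimated on 4000 genes), and a contrast that averages the 6 tissues. Differences are given with their standard errors from that fit. Whether a strain difference depends on the tissue was tested with the F test of all interaction contrasts of the same fit. The comparisons with C57BL/6J share its arrays, so calls were not compared between strains.

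Gene lists and families were fixed from general knowledge of mouse biology, some by name and some by symbol pattern. In each tissue, the share of a list's members that passed was compared with that of all other genes tested by a two-sided Fisher's exact test, adjusted over all lists and tissues. This test treats genes as independent. Members of a list can vary together on the same arrays, so its p values can be too small, and no allowance was made for this. In the report the adjusted p of these tests stands in parentheses after the counts. The number of members that pass when the F tests are adjusted over the list alone is given beside the number adjusted over all genes. Shifts of lists in the tissue-averaged contrasts were tested with limma's camera on the moderated statistics with the preset inter-gene correlation of 0.01 and again with a correlation estimated from the residuals of each list. Lists with fewer than 4 measured members were not tested. Copy-number-variable families were also compared with 10000 random gene lists of the same size matched on mean log2. For neighbours, pairs of adjacent genes that passed with the same sign and a difference of at least 0.5 were counted among 18032 ordered genes and compared with 1000 random orders (one-sided). Within-array SDs are those of 3 animals unless a standard error is named.

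The genes named are those of a fixed rule. They are, for each strain against C57BL/6J, the 5 largest increases and 5 largest decreases with the same sign in all 6 tissues. Per tissue they are the 3 largest ranges of strain means among passing genes and the 3 largest among genes passing in that tissue alone. The rule also takes the 10 largest interaction F values, for each list described the members with the largest statistic, every measured gene of known strain loci, Xist and Y-linked genes, and the longest runs of neighbours. Design, lists, naming rule and alternatives, apart from those said to be added, were set before the data were examined. Of the known strain loci, 13 were measured by a probe set of their own, and Ren1, Ren2, C4a, C4b, Entpd4, Soat1 and H2-Ea-ps were not.

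The steps were tested on simulated data with the variances of the real genes, in which each gene and array was drawn independently. Planted changes of 0.5 log2 units among strains were recovered in 86.6% of genes in brain, 59.7% in heart, 74.6% in kidney, 67.2% in liver, 65.7% in lung and 85.1% in testis, changes of 1 in 94.0% (heart) to 100.0% and changes of 2 in all, with 4 to 15 of the unchanged genes called. For the tissue-averaged contrast, simulated for DBA2/J, all planted changes of 0.5, 1 and 2 were recovered with 15 unchanged genes called. For the interaction 49.3% of changes of 0.5 and all of 1 and 2 were recovered with 90 unchanged genes called (0.5%), and 23 genes were called where none had an interaction. All 5 lists moved by 0.3 were found and none of 25 unmoved ones, and 21 neighbour pairs were found for 20 planted. The list result does not cover lists whose members vary together.

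The alternatives were another gene value (the mean of a gene's probe sets, every probe set by itself, or without probe sets whose name ends in _x_at or _s_at), a filter to genes with a mean log2 of at least 6, another quantile normalization or median centring, an intensity trend with a robust prior, array weights, a minimum difference (1 in a tissue, 0.5 averaged), the replicate number as a block, no animal block or the animal number of the source name, only the arrays of the 2 strains compared, a call on at least 2 probe sets, and leaving out each animal in turn. Fits without the 2 brain arrays nearest to each other across strains, without C57BL/6J, without C57BL/6J and 129S2, and the MHC class I list without 3 genes its pattern took in were added after the data were seen. Whether numbers pair animals across strains was checked on the residuals. Arrays of 2 strains with the same number in a tissue had median correlations across genes between −0.012 in brain and 0.102 in testis, with single pairs from −0.576 to 0.583, both in heart. The medians of arrays with other numbers were −0.0133 in testis, −0.0126 in kidney, where same-number arrays had 0.0647, and 0.0066 in brain. No pairing of strains by number was assumed, and the block was run as an alternative. In kidney, liver and testis the block cannot judge strain differences, since the C57BL/6J numbers there occur in no other strain. Arrays of the same animal in 2 tissues had a median correlation of 0.0483.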

Results

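Transcript levels were measured with Affymetrix whole-genome mouse expression arrays in 6 tissues of 6 inbred mouse strains. The strains were C57BL/6J (the strain of the mouse reference genome), A/J, DBA2/J, 129S2, C3HeB/FeJ and AKR/J, and the tissues were brain, heart, kidney, liver, lung and testis. Each of the 36 combinations of strain and tissue was measured on 3 arrays, each from a separate male of 11 to 14 weeks, giving 18 arrays per tissue. The values were the log2 signals of 45101 probe sets as the authors deposited them, and 18193 genes were tested on 1 probe set each. Array medians lay between 6.40 and 6.44 in brain, 5.08 and 5.16 in heart, 5.79 and 5.90 in kidney, 4.95 and 5.01 in liver, 6.80 and 6.83 in lung, and 5.74 and 5.78 in testis. Because medians were near equal within a tissue and differed between tissues, levels were compared only within a tissue. The number of arrays, 3 per group, limits the precision of every value.

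Tissue and sex labels were checked first. On all 18 arrays of every tissue, the markers fixed for that tissue had the highest mean of the 6 tissue lists. Lung markers such as surfactant genes averaged 13.39 in lung, and testis markers averaged 13.16 in testis. Eif2s3y, a Y-linked translation factor gene, read between 7.69 and 9.83 on all arrays. The Y-linked genes Kdm5d and Uty read as low as 3.55 and 4.67, with means of 3.78 and 5.04 in testis. Xist, the non-coding RNA that silences the second X in females, read between 4.73 and 7.78. Replicate arrays had a median correlation across probe sets between 0.995 in heart and 0.998 in brain, and the lowest was 0.980 in lung. Across the brighter genes, 16 of 18 brain arrays were nearest to an array of their own strain after the gene means were subtracted. The exceptions were brain arrays 129S2 2 and AKR/J 2, which were nearest to each other (r = 0.583 across genes). Heart array 129S2 3 was nearest to a C57BL/6J array (r = 0.320 across genes), and in kidney, liver, lung and testis all 18 arrays were nearest to their own strain.

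The first comparison asked which genes differ in level among the 6 strains within each tissue. Ugt2b38, a UDP-glucuronosyltransferase gene, had the widest difference, with strain means 9.74 log2 units apart, and read 14.22 ± 0.0314 in C3HeB/FeJ kidney and 4.49 ± 0.0410 in 129S2 kidney (mean ± SD, n = 3 each). The 129S2 value lies under the kidney array medians. No value here or below was tested against background, so wide ranges are differences of signal. Core clock genes, which drive daily rhythms, differed among strains in every tissue but testis more often than other genes. The tests of lists within tissues treat members as independent, although members can vary together, so their p values can be too small. The time of day of sampling is not given in the sources used here. By limma's moderated F test with Benjamini-Hochberg adjustment (adjusted p under 0.05), 8389 genes passed in kidney, 7371 in testis, 5913 in lung, 5756 in liver, 4203 in brain and 3824 in heart. These were 46.1%, 40.5%, 32.5%, 31.6%, 23.1% and 21.02% of the genes tested. Most differences were small. Strain means were at least 1 log2 unit apart for 923 of the passing genes in kidney, 744 in testis, 948 in lung, 1029 in liver, 299 in brain and 649 in heart. The median residual SD, which sets what each tissue could resolve, ran from 0.0907 in brain to 0.131 in heart. With a difference of at least 1 log2 unit required, liver rather than kidney had the most genes.

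**Figure D1:**
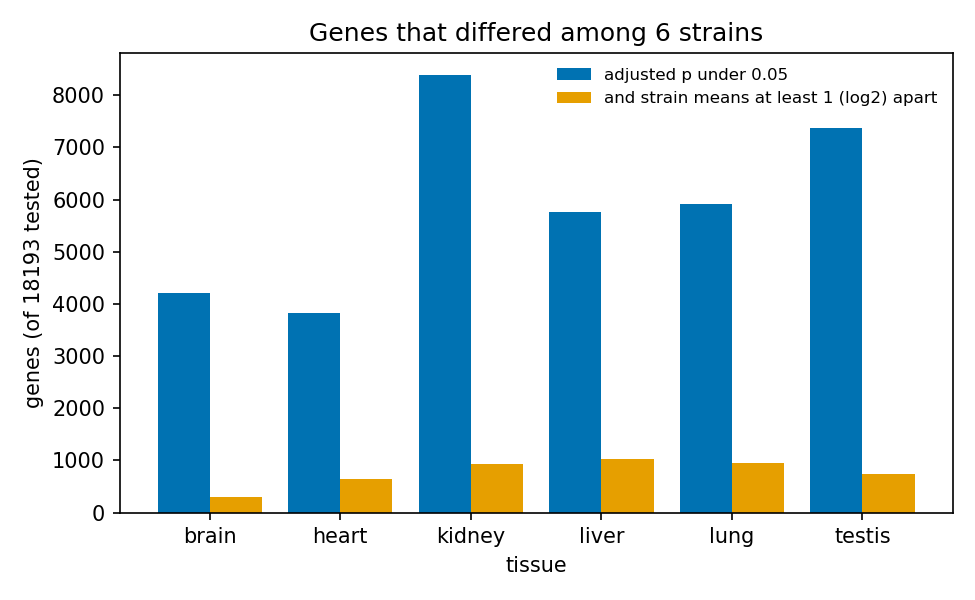
Number of genes that differed among the 6 strains in each tissue (vertical axis, genes of 18193 tested), for all genes with an adjusted p under 0.05 (blue) and for those whose strain means were also at least 1 log2 unit apart (orange). Kidney has the tallest blue bar at 8389 genes and liver the tallest orange bar at 1029.

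In brain, Scn2b, which encodes an auxiliary subunit of voltage-gated sodium channels, read 11.67 ± 0.160 in C3HeB/FeJ, 5.48 ± 0.712 in AKR/J and 5.73 ± 0.564 in 129S2 (n = 3; range 6.19, adjusted p = 1.91e-12). Gm13306 had a range of 6.10 and Rpgrip1, a ciliary protein gene needed in photoreceptors, a range of 5.12 with C57BL/6J highest at 11.16 ± 0.0872. Among genes that passed in brain and in no other tissue, the somatostatin receptor gene Sstr1 was lowest in C57BL/6J at 5.05 ± 0.575 and highest in A/J at 7.63 ± 0.101. The keratin gene Krt12 had a range of 2.24. Pmch, which encodes the hypothalamic peptide melanin-concentrating hormone, had a range of 2.23 (adjusted p = 0.0269), a call that ended with an intensity trend and robust prior (adjusted p = 0.0850), without C57BL/6J brain 2 (0.0794) and without C57BL/6J brain 3 (0.0601). Of 17 clock genes 14 passed (17 adjusted over the list alone; Fisher's exact test of the list, adjusted p = 9.34e-06), with Npas2 1.46 apart and Dbp 1.20 apart. Zinc finger genes named Zfp, a list fixed by symbol that takes in genes of the KRAB type, many of which silence transposable elements, and genes of other types, passed more often than other genes, 116 of 329 (134 adjusted over the list alone; 9.48e-06), with Zfp874a 2.79 apart and Zfp704 1.99 apart. Macrophage markers, which in brain include genes of microglia, passed in 8 of 10 (9 adjusted over the list alone; 0.00199). Cholesterol synthesis genes passed in 10 of 17 (14; 0.0116), led by Sc5d, a late enzyme of the pathway, with a range of 2.35. Immediate-early genes passed in 7 of 12 (10; 0.0428), led by Zfp36 and Btg2, and the call of Btg2 itself ended without A/J brain 1 (adjusted p = 0.0585). Choroid plexus markers passed in 6 of 8 (6; 0.0161) and fatty acid synthesis genes in 8 of 15 (12; 0.0487). Both of these last calls ended among genes with a mean log2 of at least 6 in brain (adjusted p = 0.140 and 0.142).

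In heart, Gdpd3, a lysophospholipase D gene, read 10.80 ± 0.0817 in 129S2 and 5.08 ± 0.250 in AKR/J (adjusted p = 3.41e-15). Plet1os was lowest in 129S2 at 3.52 ± 0.113, and Rpgrip1 had a range of 4.94. Bpgm, which encodes bisphosphoglycerate mutase, an enzyme of red cells, passed in heart alone and read 10.34 ± 0.409 in C57BL/6J and 7.33 ± 0.204 in DBA2/J. Erythroid markers averaged 7.78 in C57BL/6J heart and 6.54 in DBA2/J heart, and their list test did not pass (adjusted p = 0.823). The other genes that passed in heart alone with wide ranges were 1700120C14Rik (2.11) and Cpxm2 (2.05). Clock genes passed in 15 of 17 (16 adjusted over the list alone; 3.68e-07), with Dbp 3.87 apart and the repressor gene Nfil3 2.07 apart. Interferon-stimulated genes passed in 16 of 26 (20; 0.000116), led by Xaf1 and Iigp1, an immunity-related GTPase gene with a range of 1.89. Heat-shock genes passed in 8 of 10 (10; 0.00115), and Hspa1a, an inducible heat-shock protein, averaged 9.64 ± 1.91 in AKR/J and 5.66 ± 0.602 in A/J. Genes of oxidative phosphorylation passed less often than other genes, 7 of 80 (0 adjusted over the list alone; 0.0290). None of 11 heart markers passed.

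In kidney, transthyretin (Ttr), a carrier of thyroid hormone and retinol, read 13.80 ± 0.123 in AKR/J and 7.77 ± 0.194 in DBA2/J (adjusted p = 1.4e-15). Gcnt1, a glycosyltransferase gene, read 10.47 ± 0.0882 in AKR/J and 4.52 ± 0.315 in DBA2/J. Among genes that passed in kidney alone, Mep1a, which encodes the brush-border protease meprin alpha, read 13.47 ± 0.0582 in C57BL/6J and 9.57 ± 0.230 in C3HeB/FeJ. Methig1 had a range of 4.27 and Ctxn3 a range of 3.24. All 17 cholesterol synthesis genes passed (17 adjusted over the list alone; 3.19e-05), among them Sc5d (range 2.54), Idi1 (1.93), Hmgcs1 (1.33) and Nsdhl (1.13). Clock genes passed in 16 of 17 (16; 0.000784), with Arntl, the activator of the core loop, at 8.91 ± 0.0431 in DBA2/J and 5.94 in A/J. Glutathione S-transferases, which conjugate electrophiles, passed in 18 of 23 (18; 0.0159), with Gsta2 at 12.51 ± 0.0778 in 129S2 and 8.81 ± 0.178 in DBA2/J. Interferon-stimulated genes passed in 22 of 26 (22; 0.000908), fatty acid synthesis genes in 13 of 15 (13; 0.0161), kidney markers in 10 of 10 (10; 0.00338), MHC class II genes in 10 of 11 (10; 0.0211), macrophage markers in 9 of 10 (9; 0.0369) and heat-shock genes in 9 of 10 (9; 0.0369). These 6 calls ended among genes with a mean log2 of at least 6 in kidney, with adjusted p values of 0.140, 0.30, 0.0811, 0.228, 0.152 and 0.321. Lymphocyte markers (0 of 10; 0.0159) and neutrophil markers (0 of 8; 0.0428) passed less often than other genes. For these lists no result among genes with a mean log2 of at least 6 in kidney is given. Low signal is therefore not told apart from a lack of strain differences.

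In liver, Obp2a, an odorant-binding lipocalin gene, read 11.39 ± 0.733 in DBA2/J and 4.07 ± 0.709 in A/J (adjusted p = 3.54e-09). Cytochrome P450 genes, which oxidise lipids, steroids and foreign compounds, passed in 39 of 56 (39 adjusted over the list alone; 3.68e-07). Cyp4a14 read 11.21 ± 0.757 in 129S2 and 4.30 ± 0.341 in C3HeB/FeJ, Cyp2b9 read 10.47 ± 0.692 in A/J and 3.57 ± 0.232 in 129S2, and Cyp2c39 read 11.60 ± 0.186 in A/J and 4.84 ± 0.0551 in C57BL/6J. Targets of PPAR alpha, a fatty acid sensor, passed in 16 of 17 (16; 4.63e-06), led by the pantetheinase gene Vnn1 with a range of 3.61. Glutathione S-transferases passed in 20 of 23 (20; 2.8e-06) and UDP-glucuronosyltransferases in 9 of 10 (9; 0.00199), with Gstt2 2.08 and Ugt3a2 6.04 apart. Complement genes passed in 17 of 21 (18; 6.68e-05). Hc, which encodes complement C5, read 13.03 ± 0.108 in C57BL/6J and 10.69 in A/J, C6 read 11.80 ± 0.0240 in C57BL/6J and 9.13 ± 0.477 in A/J, and C9 was 1.30 apart. All 17 clock genes passed (17; 3.67e-07), and Dbp read 11.58 ± 0.0433 in A/J and 5.63 ± 0.678 in C57BL/6J. Interferon-stimulated genes passed in 23 of 26 (24; 3.67e-07), with Ifi27 2.01 and Bst2 1.20 apart. Fatty acid synthesis genes passed in 13 of 15 (14; 0.000215), macrophage markers in 9 of 10 (9; 0.00199), heat-shock genes in 9 of 10 (9; 0.00199) and acute-phase genes in 11 of 16 (12; 0.0159). Macrophage markers averaged 8.67 in C57BL/6J liver and 7.61 in C3HeB/FeJ liver. The acute-phase gene Saa1 averaged 12.49 ± 2.12 in C57BL/6J and 8.43 in 129S2. The calls of UDP-glucuronosyltransferases, heat-shock genes and acute-phase genes ended among genes with a mean log2 of at least 6 in liver (adjusted p = 0.140, 0.140 and 0.639).

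In lung, Serpina1b, an alpha-1-antitrypsin paralog, read 11.58 ± 0.0255 in DBA2/J and 4.59 ± 0.292 in C57BL/6J (adjusted p = 5.53e-10). Jchain, which joins polymeric antibodies, read 13.42 ± 0.129 in 129S2 and 6.67 ± 0.0891 in DBA2/J. Immunoglobulin genes passed in 19 of 22 (19 adjusted over the list alone; 7.8e-06) and averaged 8.27 in 129S2 and 6.07 in DBA2/J, with Igkv6-14 4.96 and Igkv8-30 4.30 apart. Ankrd33b had a range of 5.83. Among genes that passed in lung alone, the neutrophil granule gene Ltf (10.26 ± 0.885) and the neutrophil chemokine gene Cxcl5 (6.87 ± 0.835) were highest in DBA2/J, with ranges of 3.29 and 3.18. Neutrophil markers averaged 9.15 in C57BL/6J lung and 7.26 in 129S2 lung, and their list test did not pass (4 of 8, 7 adjusted over the list alone, adjusted p = 0.517). Adipoq, the adipocyte hormone adiponectin, read 10.39 ± 1.27 in C3HeB/FeJ (range 3.46, adjusted p = 0.0323), and its call ended with an intensity trend and robust prior (0.0797) and without A/J lung 1 (0.0615), A/J lung 3 (0.0538), C3HeB/FeJ lung 1 (0.0619) or C3HeB/FeJ lung 3 (0.0891). Adipose markers averaged 10.66 on lung array C3HeB/FeJ 3 and 9.36 on the next array, and skeletal muscle markers averaged 11.06 there and 6.36 on the next. Macrophage markers passed in 9 of 10 (10; 0.0023), and Marco, a scavenger receptor of alveolar macrophages, read 9.23 in 129S2 and 5.90 in DBA2/J. Cholesterol synthesis genes passed in 15 of 17 (17; 4.85e-05) and clock genes in 16 of 17 (16; 6.04e-06). Zinc finger genes named Zfp passed in 143 of 329 (153; 0.000367), heat-shock genes in 8 of 10 (9; 0.0162), smooth muscle markers in 6 of 7 (6; 0.0309) and lung markers in 7 of 9 (7; 0.0360). These 4 calls ended among genes with a mean log2 of at least 6 in lung (adjusted p = 0.228, 0.0981, 0.140 and 0.140). Oxidative phosphorylation genes (7 of 80, 4 over the list, 1.58e-05) and ribosomal protein genes (7 of 46, 7 over the list, 0.0494) passed less often than other genes.

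In testis, 1700104B16Rik read 10.18 ± 0.0371 in C57BL/6J and 3.91 ± 0.165 in AKR/J, and Galntl6, a glycosyltransferase gene, read 9.94 ± 0.149 in C57BL/6J and 4.09 ± 0.0853 in C3HeB/FeJ. Pga5, a pepsinogen gene, read 10.92 ± 0.113 in A/J and 5.42 ± 0.0382 in 129S2 (adjusted p = 3.57e-18). All 3 passed in testis and in no other tissue. Leydig cell markers, genes of androgen synthesis, passed in 5 of 5 (5 adjusted over the list alone; 0.0491), with Hsd17b3 at 10.40 ± 0.0865 in AKR/J and 8.60 in C57BL/6J and Cyp17a1 1.05 apart. Macrophage (7.28), adipose (6.86) and smooth muscle markers (8.83) also averaged highest in AKR/J testis, the last with array AKR/J 2 apart at 9.40 (next array 8.79). The list test of macrophage markers did not pass in testis (adjusted p = 0.0778). Glutathione S-transferases passed in 17 of 23 (17; 0.0143), with Mgst2 1.39 and Gsta3 1.53 apart. The Leydig and glutathione S-transferase calls ended among genes with a mean log2 of at least 6 in testis (adjusted p = 0.171 and 0.143). Cytochrome P450 genes passed less often than other genes, 12 of 56 (9; 0.0211), although Cyp2c55 had a range of 3.49. Among P450 genes with a mean log2 of at least 6 the difference turned, with 7 of 9 passing (adjusted p = 0.341). Immunoglobulin genes passed in 1 of 22 (0; 0.00221), and the 1 that did, Ighmbp2, was taken into the list by its symbol and encodes no immunoglobulin. This call also ended among genes with a mean log2 of at least 6, where 2 of 4 passed (adjusted p = 1). Clock genes passed in 9 of 17 (adjusted p = 0.566).

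Olfactory receptor genes passed less often than other genes in every tissue, in 1 of 39 in brain, 1 in heart, 6 in kidney, 3 in liver, 0 in lung and 2 in testis. The adjusted p of these tests ran from 8.22e-06 in lung to 0.0159 in heart, and adjusted over the list alone 0, 0, 2, 0, 0 and 1 passed. No result among genes with a mean log2 of at least 6 is given for this list. Low signal is therefore not told apart from a lack of strain differences. Sulfotransferases, MHC class I genes and the markers of brain, heart, liver, testis, adipose tissue, brown fat, skeletal muscle, epididymis, exocrine pancreas, erythroid cells and thymus did not pass the list test in any tissue (lowest adjusted p 0.0710, MHC class I genes in brain). Among genes with a mean log2 of at least 6 in the tissue, 9 list tests passed that had not passed over all genes. Heart markers passed less often than other genes in heart (adjusted p = 0.0397), zinc finger genes named Zfp in kidney (53.9% against 66.2%, 0.00499, opposite to brain), oxidative phosphorylation genes in brain, liver and testis (0.0174, 5.5e-05 and 0.0157) and ribosomal protein genes in kidney and liver (8.16e-05 and 0.0202). Cytochrome P450 genes in kidney (0.0371) and MHC class II genes in heart (0.036) passed more often. Of the 18193 genes, 21.2% passed in no tissue, 26.2% in 1 tissue, and 3.57%, or 650 genes, in all 6. Among the 6997 genes with a mean log2 of at least 6 in every tissue, 8.49% passed in all 6 tissues.

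Clock genes were followed across strains because they differed in 5 of the 6 tissues. Sampling times are not given in the sources used here. Strain differences of the clock and different times of sampling therefore cannot be told apart. In liver, Dbp, a clock output gene, averaged 5.63 in C57BL/6J, 6.39 in DBA2/J, 8.60 in C3HeB/FeJ, 10.95 in 129S2, 11.11 in AKR/J and 11.58 in A/J. In kidney the same gene averaged 8.55 in C57BL/6J and 7.86 in DBA2/J against 11.78 in A/J. In lung, C57BL/6J averaged 11.51, near A/J at 11.83, while DBA2/J averaged 7.72. In heart, C57BL/6J averaged 9.98 and DBA2/J 6.59. There 129S2 animals 1, 2 and 3 read 7.61, 8.93 and 10.17, and in lung they read 8.56, 10.9 and 11.71. In brain, C57BL/6J averaged 10.67, between A/J at 11.11 and DBA2/J at 9.91. The C57BL/6J animals of kidney, liver and testis (10, 11 and 12 in the titles) were not those of brain, heart and lung (2, 3 and 4).

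**Figure D2:**
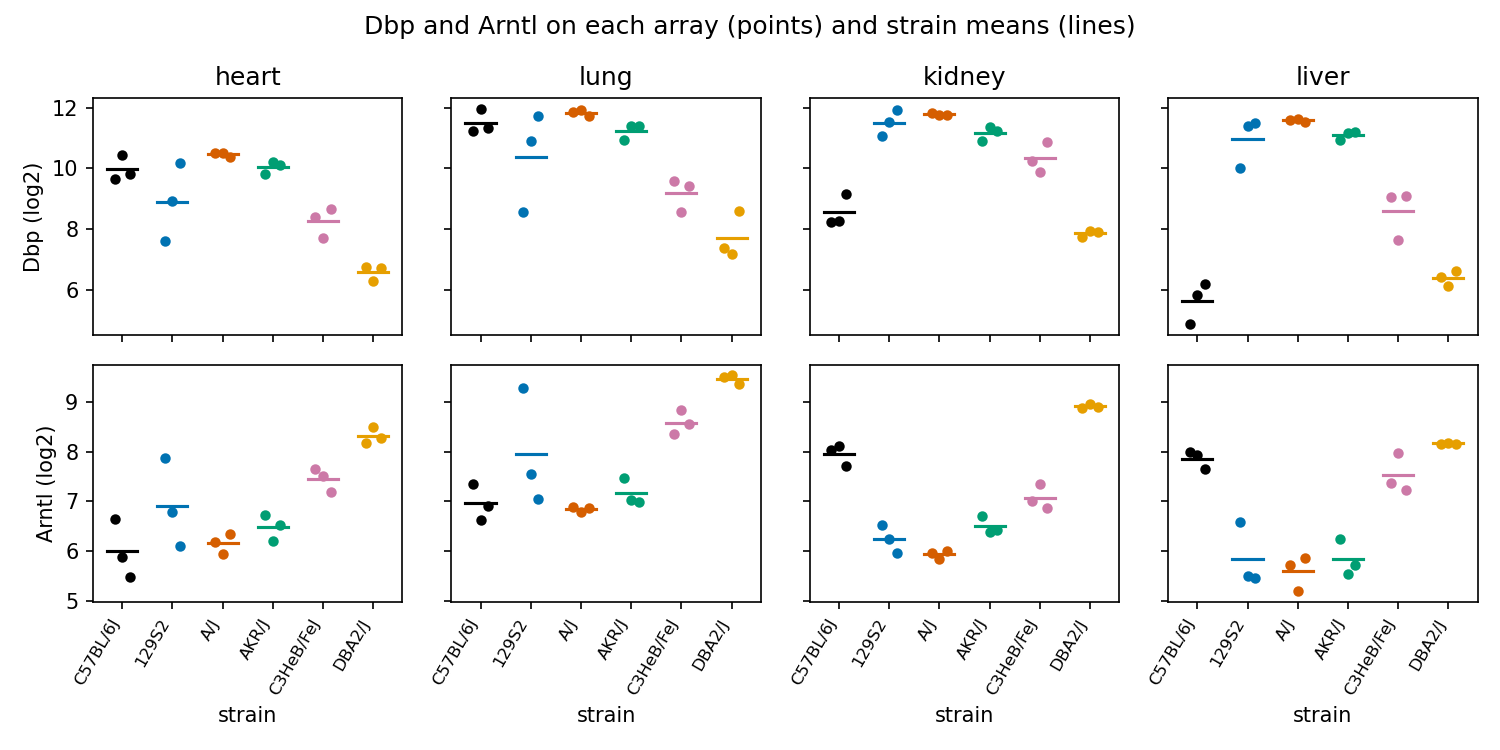
Levels (log2) of Dbp (top) and Arntl (bottom) on each array (points) with the mean of each strain (lines) in heart, lung, kidney and liver. C57BL/6J lies high for Dbp in heart (9.98) and lung (11.51) and low in liver (5.63), and Arntl runs opposite to Dbp.

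The second comparison asked how each strain differs from C57BL/6J when the 6 tissues are averaged. The widest decrease in 4 of the 5 strains was in Rpgrip1, which was lower by 4.30 ± 0.0474 log2 units in 129S2 (SE; −4.30), −4.33 in A/J, −4.31 in AKR/J and −4.33 in C3HeB/FeJ, and by less in DBA2/J (−2.79). Only 1 of its 4 probe sets had this decrease in each strain, and in 129S2 another went the opposite way. Gdpd3 was higher in 129S2 (+3.93 ± 0.131). The transmembrane protein gene Tmem87a was higher in all 5 strains, by 2.53, 2.61, 2.57, 2.47 and 2.60 in 129S2, A/J, AKR/J, C3HeB/FeJ and DBA2/J. H2-K1, a classical MHC class I gene, was lower in A/J (−2.99), AKR/J (−3.22) and C3HeB/FeJ (−3.26), with at least 3 of its 4 probe sets going the same way. By limma, with the animal as a random block, 5395 genes differed in 129S2 (2951 higher, 2444 lower), 5400 in A/J (3101 and 2299), 4850 in AKR/J (2889 and 1961), 5165 in C3HeB/FeJ (3029 and 2136) and 5371 in DBA2/J (3138 and 2233). In 129S2 decreases were 45.3% of these genes, and 55.1% with arrays centred on the median. With a difference of at least 0.5 also required, 390, 376, 333, 374 and 371 remained, of which 61.3%, 58.2%, 56.2%, 54.3% and 60.1% were lower than in C57BL/6J. Among genes with a mean log2 of at least 6 the share of decreases was 47.1% in AKR/J and 49.6% in C3HeB/FeJ.

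Further genes among the widest differences with 1 sign in all 6 tissues were these. Mndal, of the interferon-activated PYHIN family, was lower in A/J (−2.96), AKR/J (−3.07) and DBA2/J (−2.99), with both probe sets agreeing. Ifi202b, of the same family, was higher in AKR/J (+2.47 ± 0.0685) and DBA2/J (+2.37). Gbp2b, a guanylate-binding protein gene, was higher in A/J (+2.29 ± 0.0860). H2-D1 was lower in AKR/J (−2.63) by the probe set used, while of its 9 probe sets 4 went the same way and 4 the opposite way. Serpina1b was higher in DBA2/J (+2.55, both probe sets). Cap1, an actin regulator gene, was higher in 129S2 (+2.11), A/J (+2.27), C3HeB/FeJ (+2.26) and DBA2/J (+2.21), with both probe sets agreeing. Abhd1 was higher in 129S2 (+2.22), A/J (+2.44), AKR/J (+2.42) and C3HeB/FeJ (+2.43).

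Further increases were those of the syndecan gene Sdc4 in 129S2 and AKR/J (both +2.3), Hddc3 in A/J (+1.99), AKR/J (+2.05) and C3HeB/FeJ (+1.91), AI506816 in DBA2/J (+2.21) and the RNA-binding protein gene Rbm45 in C3HeB/FeJ (+2.10). For Sdc4 and for Hddc3, 1 of 2 probe sets went the opposite way. Further decreases were those of Ankrd33b (−3.45, 1 of 3 probe sets) and Galc, the lysosomal galactosylceramidase gene (−2.66, 1 of 3 probe sets and 1 opposite), in 129S2, Tmem267 in 129S2 (−2.90), C3HeB/FeJ (−2.96) and DBA2/J (−3.06), Zfp874a in 129S2 (−2.30) and A/J (−2.29), and Mir1931 in A/J (−2.31) and AKR/J (−2.34). Gm13306 was lower in C3HeB/FeJ (−3.30) and DBA2/J (−3.34). Pdxdc1 was lower in C3HeB/FeJ (−3.03) and DBA2/J (−3.05), but its call ended when its 4 probe sets were averaged (−0.02 with adjusted p = 0.651 and −0.01 with 0.753). All of these named calls had adjusted p values from limma between 1.44e-76 and 1.17e-27.

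Genes of loci known to vary between mouse strains were examined one by one. Glo1, the glyoxalase gene of a segment known to be duplicated in several strains, was higher than in C57BL/6J by 1.39 in 129S2, 1.61 in A/J, 0.95 in AKR/J, 1.04 in C3HeB/FeJ and 1.03 in DBA2/J (SE 0.0458 in A/J), with 4 of 4 probe sets agreeing. Alad, a heme synthesis gene known to be duplicated in some strains, was higher by 1.05, 1.56, 1.49, 1.52 and 1.44 in the same order (SE 0.0335 in A/J), with 2 of 2 probe sets agreeing. Nnt, the mitochondrial transhydrogenase gene in which C57BL/6J is known to carry a deletion, was higher by 0.72, 1.04, 0.96, 0.69 and 0.62, with 2 of 3 probe sets agreeing, although its call among strains in heart ended when probe sets were averaged (adjusted p = 0.0540). That heart call also ended with the replicate number as a block (moderated F test, adjusted p = 0.104). It ended too without any 1 of A/J 1, 2 and 3, AKR/J 1, 2 and 3 and C57BL/6J 3 and 4. With these arrays left out in turn the adjusted p was at most 0.0762 (without C57BL/6J 3). The sign held in all 6 tissues for Glo1 and Alad. For Nnt the lowest difference in a tissue was −0.098 in 129S2, −0.026 in C3HeB/FeJ and −0.15 in DBA2/J. H2-Ea, the MHC class II gene known to be silent in the C57BL/6J haplotype, read 12.31 ± 0.124 in DBA2/J lung against 8.24 in C57BL/6J. The other strains lay far nearer to C57BL/6J in lung, at 7.85 in 129S2, 9.32 in A/J, 9.17 in AKR/J and 9.05 in C3HeB/FeJ. Averaged over tissues, H2-Ea was higher by 0.186, 0.20 and 0.155 in A/J, AKR/J and C3HeB/FeJ, with 2 of 3 probe sets agreeing. The A/J call ended without A/J 2 (limma, adjusted p = 0.0593), and 129S2 did not differ (−0.029). Sequence differences under the probes were not tested, so these values do not show whether the gene is silent in these strains. Klrd1, a natural killer cell receptor gene known to be deficient in DBA2/J, read 4.75 ± 0.132 in DBA2/J lung against 8.06 ± 0.270 in C57BL/6J. Hc, in which A/J, AKR/J and DBA2/J are known to carry a frameshift, was lower in A/J (−0.70), AKR/J (−0.59) and DBA2/J (−0.46), and in liver read 10.69, 11.12 and 11.45 against 13.03 in C57BL/6J.

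Gabra2, a GABA receptor subunit gene with a known intronic deletion in C57BL/6J, passed in brain alone and read 7.47 there in C57BL/6J, 1.07 to 1.43 below the other strains. Gpnmb, known to be truncated in DBA2/J, was lower in DBA2/J (−0.45), most in lung (6.51 against 8.15). Dysf, the dysferlin gene known to be disrupted in A/J, was lower in A/J (−0.57) and read 5.68 in A/J lung against 7.28. Aox3, an aldehyde oxidase gene, was lower in DBA2/J (−0.97) and read 10.58 in its liver against 12.50. Ide, the insulin-degrading enzyme gene known to have gained copies in some C57BL/6J mice, was lower than in C57BL/6J by −0.35, −0.40, −0.31, −0.28 and −0.32 in 129S2, A/J, AKR/J, C3HeB/FeJ and DBA2/J. It passed in kidney, liver and testis, where the SD of C57BL/6J was 0.228, 0.257 and 0.188, and not in brain, heart or lung. The former tissues come from C57BL/6J animals 10, 11 and 12 and the latter from animals 2, 3 and 4. Tissue and animal set therefore coincide, and the averages of Ide take in both sets. In brain C57BL/6J read 9.21, within the 9.20 to 9.33 of the other strains. Mx1 passed in kidney and testis with ranges of 0.24 and 0.39, and Itln1 passed in no tissue and, averaged over tissues, only in DBA2/J (+0.25, adjusted p = 0.00147). The replicate number as a block cannot judge the calls of Mx1, since the C57BL/6J numbers in kidney and testis occur in no other strain. The kidney call of Mx1 ended with an intensity trend and robust prior (moderated F test, adjusted p = 0.0804). It ended too without any 1 of C57BL/6J 10, 11 and 12, AKR/J 1 and 3 and C3HeB/FeJ 3 (adjusted p of at most 0.0782). The testis call ended without any 1 of 129S2 3 and 4, A/J 1 and 2, C3HeB/FeJ 1 and 2 and DBA2/J 2 (at most 0.107).

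**Figure D3:**
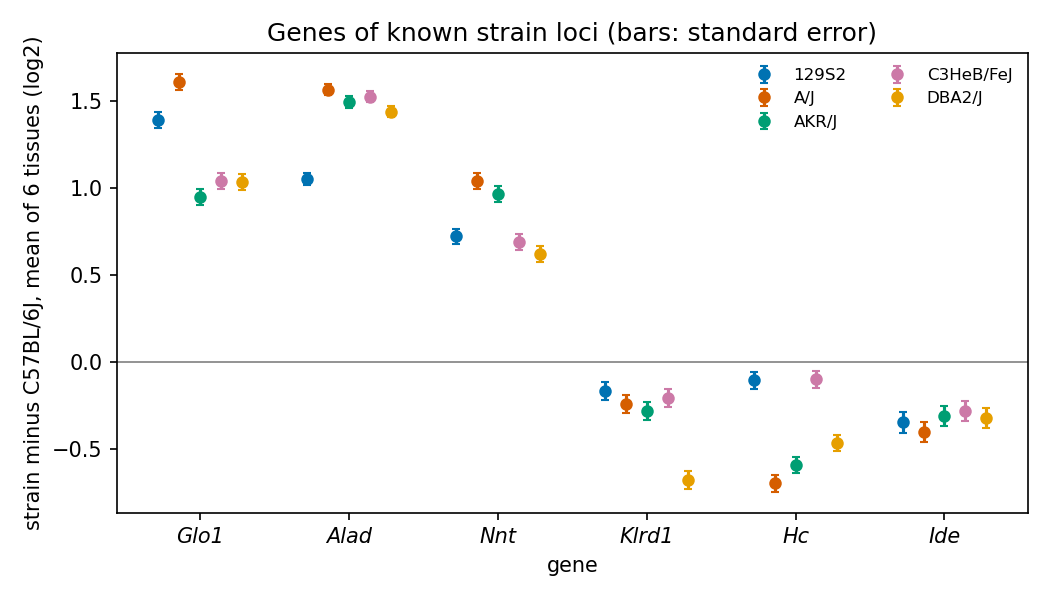
Difference between each of 5 strains and C57BL/6J (vertical axis, log2, mean of 6 tissues; bars give the standard error) for 6 genes of known strain loci. Glo1, Alad and Nnt lie above 0 in all 5 strains, with Glo1 highest in A/J at 1.61, and Klrd1 lies lowest in DBA2/J at −0.68.

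Interferon-stimulated genes were lower as a group in 129S2 than in C57BL/6J, with a mean of −0.39 over 26 genes, 21 lower and 1 higher (23 and 1 adjusted over the list alone; camera adjusted p = 3.11e-14). Bst2, which tethers virus particles, was lower by −0.64, Oasl2 by −0.88 and the interferon feedback gene Usp18 by −0.66. Xaf1 was lower by −1.31 on the probe set used and higher (+0.72) when its 2 probe sets were averaged. MHC class I genes, which present peptides to T cells, had means of −0.46 in C3HeB/FeJ (7 lower and 3 higher of 16; 1.93e-08), −0.43 in AKR/J (6 and 2; 9.69e-08) and −0.27 in A/J (6 and 2; 0.000775), and adjusted over the list alone the counts were 7 and 3, 6 and 2, and 6 and 2. The medians lay far nearer to 0 than the means, at −0.04 in C3HeB/FeJ, −0.0016 in AKR/J and +0.0081 in A/J, where the sign is opposite to that of the mean, and H2-K1 had the widest decrease in each. H2-D1 was next in C3HeB/FeJ (−2.75) and AKR/J (−2.63), and of its 9 probe sets 4 went the same way and 4 the opposite way in AKR/J. Sequence differences under the probes were not tested. The means therefore rest on few genes and do not show a fall of class I genes as a whole. The symbol pattern of this list also took in H2-DMa, H2-DMb2 and H2-Ke6, which are not class I genes. Without them, a choice made after the data were seen, the means of the 13 left were −0.54, −0.51 and −0.33. MHC class II genes, which present extracellular antigens, had a mean of −0.48 in AKR/J (5 lower and 1 higher of 11, also 5 and 1 adjusted over the list alone; 2.27e-07), with H2-Aa at −1.35, H2-Ab1 at −1.33, H2-Eb1 at −1.16 and Cd74 at −0.95, and a median of −0.10. Of the 26 list shifts with adjusted p under 0.05, these 5 also passed with an estimated correlation between members, at adjusted p = 0.0403 for interferon-stimulated genes in 129S2, 5.61e-05, 0.000106 and 0.0481 for MHC class I genes in C3HeB/FeJ, AKR/J and A/J, and 0.0497 for MHC class II genes in AKR/J, each with an estimated correlation.

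The other 21 shifts were lost with an estimated correlation. MHC class II genes were lower in C3HeB/FeJ (mean −0.42, median −0.055, 5 of 11 lower, 5 adjusted over the list alone; 1.65e-05; adjusted p = 0.188 with an estimated correlation) and A/J (mean −0.24, median −0.016, 5 lower, 5 over the list, 0.0304; adjusted p = 0.998 with an estimated correlation). Immunoglobulin genes were higher in 129S2 (16 of 22, 16 over the list, mean +0.33; 7.66e-05; adjusted p = 0.210 with an estimated correlation), with Jchain at +1.30 and Igha at +1.11. Interferon-stimulated genes were lower in A/J (19 of 26, 20 over the list, 1.48e-05), C3HeB/FeJ (17, 18 over the list, 9.59e-05), DBA2/J (9, 10 over the list, 0.00689) and AKR/J (11, 11 over the list, 0.00909), with adjusted p = 0.693, 0.858, 0.998 and 0.998 with an estimated correlation. Macrophage markers were lower in 129S2 (7 of 10, 8 over the list, 1.91e-05), DBA2/J (8, 9 over the list, 7.66e-05), C3HeB/FeJ (7, 8 over the list, 0.00142) and A/J (6, 6 over the list, 0.00474), with adjusted p = 0.605, 0.693, 0.963 and 0.998 with an estimated correlation. The complement gene C1qc, also a macrophage marker, was at −0.62 in 129S2 and the lysosomal protease gene Ctss at −0.77. Complement genes were lower in A/J (10 of 21, 10 over the list, 0.00175), DBA2/J (9, 9 over the list, 0.0120), AKR/J (10, 10 over the list, 0.0275) and 129S2 (7, 7 over the list, 0.0437), with adjusted p = 0.380, 0.693, 0.858 and 0.963 with an estimated correlation, and C6 was at −0.67 in A/J.

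Heat-shock genes were higher in AKR/J (6 of 10, 6 over the list, mean +0.54; 0.0104), with Hspa1a at +1.83 and Hspa1b at +1.74, and lower in 129S2 (7, 10 over the list, 0.00473) and A/J (6, 9 over the list, 0.00473), each with adjusted p = 0.998 with an estimated correlation. Immediate-early genes were higher in A/J (9 of 12, 10 over the list, mean +0.44; 0.0359), with Junb at +0.80 and Dusp1 at +0.69, cholesterol synthesis genes were lower in C3HeB/FeJ (9 of 17, 10 over the list, 0.0149), with Sc5d at −0.70, and ribosomal protein genes were lower in A/J (8 of 46 lower and 5 higher, the same over the list, 0.0342), with Rps4l at −1.97 and Rps6 at −1.23. These 3 also had adjusted p = 0.998 with an estimated correlation. Of these 21 shifts, 7 also ended without a single animal. They were heat-shock genes in AKR/J without AKR/J 3 (mean +0.38, adjusted p = 0.179) and complement genes in AKR/J without C57BL/6J 4 (0.0583). Cholesterol synthesis genes in C3HeB/FeJ ended without C3HeB/FeJ 2 (mean −0.085 rather than −0.166, adjusted p = 0.258). In A/J, MHC class II genes ended without A/J 1, A/J 3 or C57BL/6J 4 (0.0542, 0.113 and 0.0583), ribosomal protein genes without A/J 1, A/J 3 or C57BL/6J 12 (0.0542, 0.103 and 0.0564), and immediate-early genes without A/J 1, A/J 2, C57BL/6J 3 or C57BL/6J 4 (0.0542, 0.0735, 0.0681 and 0.0816). Complement genes in 129S2 ended without any 1 of 129S2 3 and 4, C57BL/6J 4, 10 and 11 and DBA2/J 1 (adjusted p from 0.0505 to 0.0913).

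The third comparison asked for which genes the strain difference depends on the tissue. Cyp2c39 was higher in A/J than in C57BL/6J by 6.75 log2 units in liver and differed by −0.03 in testis. In liver C57BL/6J read 4.84, under the array medians there, and whether the gene had signal in testis was not tested. 1700104B16Rik was lower in AKR/J than in C57BL/6J by −6.27 in testis and differed by 0.18 in liver, and Galntl6 was lower in C3HeB/FeJ by −5.86 in testis and differed by 0.31 in brain. Nlrp12, an inflammasome-related receptor gene, was lower in 129S2 than in C57BL/6J by −5.78 in liver and differed by 0.08 in heart. By limma's interaction F test 13172 genes, 72.4% of those tested, had strain differences that depended on the tissue, and the adjusted p of the 10 genes with the largest F ran from 2.4e-62 to 1.44e-51. For C57BL/6J, all animals differed between brain, heart and lung on the one side and kidney, liver and testis on the other, so tissue and animal set coincide for this strain. For 129S2 they coincide only in part, since animals 2 and 3 served both sets of tissues and animals 1 and 4 only one set each.

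The fourth comparison took up copy number, the subject of the series title. DNA copy number was not analysed here, so genes of families known to vary in copy number between mouse strains were compared with all other genes. Every one of the 6 guanylate-binding protein genes and 7 of 8 genes of the interferon-activated PYHIN type, both induced by interferon, differed among strains in at least 3 tissues, as did 6 of 7 mu-class glutathione S-transferases and 4 of 4 Gvin and Irg genes. All 7 Ugt2b genes and all 6 Ces1 carboxylesterase genes differed in liver. Immunoglobulins differed in 18 of 21 in lung, killer lectin-like receptors in 10 of 18 in lung, kallikreins in 10 of 20 in kidney and Speer genes, which are expressed in spermatids, in 7 of 8 in testis. Vomeronasal receptors differed in any tissue in only 10 of 32 and the prolactin family in 4 of 17. The families named were picked by their counts. Over all 303 family members 67.66% differed in at least 1 tissue, against 78.97% of the other genes, and 4.62% against 3.555% differed in all 6 tissues.

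Taken as a set of 303 genes, the families passed less often than other genes in brain (14.9% against 23.2%, odds ratio 0.576, Fisher's exact test, adjusted p = 0.0013), heart (15.8% against 21.1%, 0.704; 0.0409), kidney (37.3% against 46.3%, 0.691; 0.00406) and testis (27.1% against 40.7%, 0.540; 6.74e-06). The heart call ended without any 1 of DBA2/J 1, DBA2/J 2 and C3HeB/FeJ 2 (−3.75, −4.46 and −2.95 points, adjusted p = 0.137, 0.0687 and 0.301), and the kidney call without C57BL/6J 12 (−5.55 points, 0.0812). In liver (30.4% against 31.7%; 0.663) and lung (30.4% against 32.5%; 0.550) the test did not pass. Without immunoglobulin and MHC genes the lung difference was −7.88 points and passed (Fisher's exact test, adjusted p = 0.00901). Adjusted over the list alone, 41, 39, 111, 90, 92 and 72 members passed in brain, heart, kidney, liver, lung and testis. The direction turned with signal. Among genes with a mean log2 of at least 6 in the tissue, the families passed more often in liver (74.7% against 53.7%; adjusted p = 0.000478), lung (61.2% against 43.0%; 0.000478) and kidney (78.8% against 65.8%; 0.0346), and by 8.14, 8.92 and 6.66 points in brain, heart and testis (0.242, 0.242 and 0.280). Against 10000 random gene lists matched on mean log2, their share was higher by 3.23 points in brain (permutation adjusted p = 0.076), 5.84 in heart (0.0015), 10.8 in kidney, 9.48 in liver, 10.4 in lung (4e-04 each) and 5.06 in testis (0.028).

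**Figure D4:**
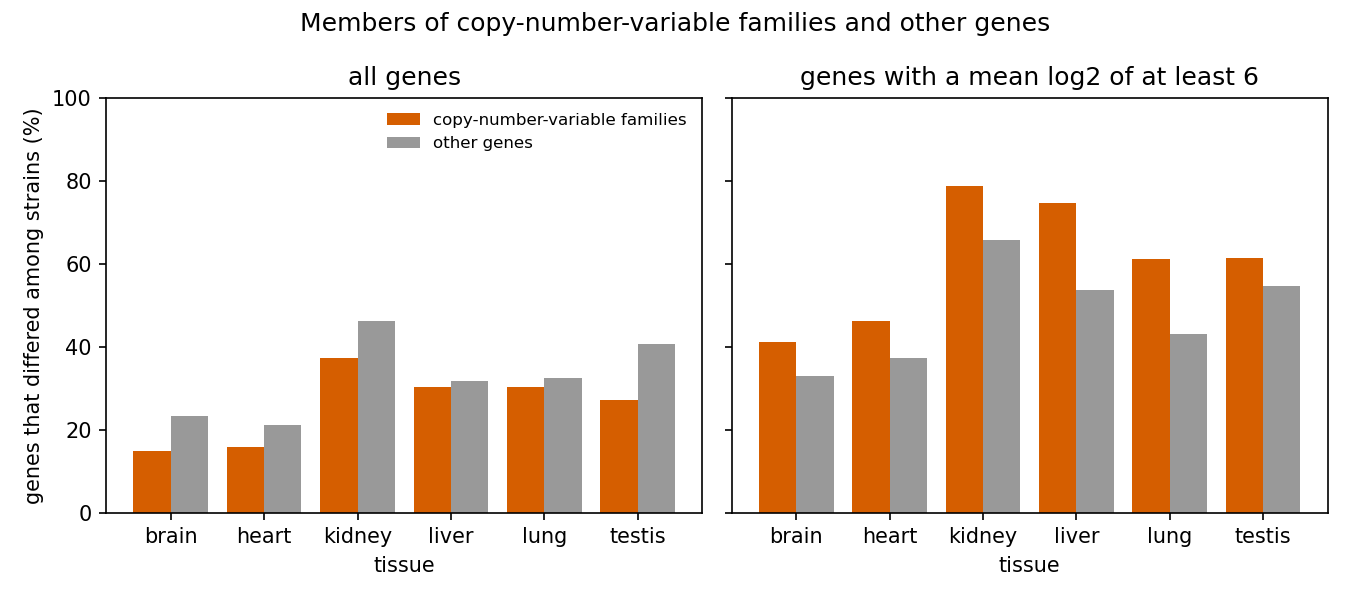
Percentage of genes that differed among strains in each tissue (vertical axis), for members of copy-number-variable families (orange) and all other genes (grey), over all genes (left) and over genes with a mean log2 of at least 6 in the tissue (right). In liver the orange bar stands at 30.4% against 31.7% on the left and at 74.7% against 53.7% on the right.

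The fifth comparison asked whether genes that differ from C57BL/6J in the same direction lie next to each other, as genes of a shared segment would. Neighbours that vary together for another reason, such as markers of the same cells, would give the same result. The comparison with random orders cannot tell these apart. In A/J, Glo1 and its neighbours 1700097N02Rik and Dnah8 were higher together, by 1.61, 0.93 and 0.58. The MHC class II genes H2-Ab1, H2-Aa and H2-Eb1 were lower together in A/J (−0.89, −0.73 and −0.80) and in C3HeB/FeJ (−1.23, −1.13 and −0.99). The same genes were also lower in AKR/J (−1.335, −1.351 and −1.156). In AKR/J, Pomt1, Uck1 and Swi5 were higher by 1.12, 0.93 and 0.88, and in DBA2/J the kallikrein genes Klk1b27, Klk1b16 and Klk1b24 were lower by −0.61, −0.53 and −0.69. In 129S2, C1qb, C1qc and C1qa, the chains of complement C1q, were lower by −0.65, −0.62 and −0.64, and Ap1s3 and Wdfy1 were higher by 0.52 and 1.79. H2-D1, H2-Q2 and H2-Q5 were lower in C3HeB/FeJ (−2.75, −0.59 and −0.50), although H2-Q5 was at +0.035 when its probe sets were averaged. Of the 9 probe sets of H2-D1, 4 went the same way and 4 the opposite way in AKR/J. Znf41-ps, Gm13238 and 1700095A21Rik were lower in AKR/J (−0.94, −0.65 and −0.57) and C3HeB/FeJ (−0.66, −0.60 and −0.59).

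Among 18032 genes in the order of the GRCm38.p6 gene table, pairs of adjacent genes that both differed by at least 0.5 in the same direction numbered 23 in 129S2, 22 in A/J, 19 in AKR/J, 28 in C3HeB/FeJ and 19 in DBA2/J. In 1000 random orders the mean was 4.39, 4.01, 3.04, 3.92 and 3.83 and the highest 12, 11, 10, 13 and 11 (permutation p = 0.001 for each, the smallest these orders can give). Without pairs of like symbols, such as members of a tandem family, the counts were 12, 12, 10, 17 and 7, and the call in DBA2/J ended (permutation p = 0.061). With a difference of at least 1 the counts were 2, 1, 4, 3 and 1, and the calls in A/J (permutation p = 0.076) and DBA2/J (0.15) ended. With both conditions the counts were 1, 1, 0, 2 and 1, and only the call in C3HeB/FeJ held (permutation p = 0.11, 0.073, 1, 0.005 and 0.14).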

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

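The tests for RNA of both strains and for exchanged labels on a pair of brain arrays, all tests of the clock genes, and the permutation test of the probe sets were chosen after the results were seen, whereas the test for animals that carry genes of both strains, the other tests of the decreases and the splits of the samples were chosen before.

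For 10 genes, those with the largest F of limma's interaction test, the difference between the same strains was not the same in 2 tissues. Nlrp12 (129S2 minus C57BL/6J) was at 0.08 in heart and −5.78 in liver, 5.86 apart. Galntl6 (C3HeB/FeJ minus C57BL/6J) was at 0.31 in brain and −5.86 in testis, 6.17 apart. 9430014N10Rik (A/J minus C57BL/6J) was at 4.06 in testis and −0.07 in kidney, 4.13 apart. Pga5 (129S2 minus A/J) was at 0.04 in kidney and −5.50 in testis, 5.54 apart. Gm7969 (C3HeB/FeJ minus C57BL/6J) was at 0.24 in lung and −5.32 in liver, 5.56 apart. Grtp1 (129S2 minus DBA2/J) was at 0.27 in heart and −4.80 in testis, 5.07 apart. 1700104B16Rik (AKR/J minus C57BL/6J) was at 0.18 in liver and −6.27 in testis, 6.45 apart. 1700095A21Rik (C3HeB/FeJ minus DBA2/J) was at 0.13 in lung and −5.49 in testis, 5.62 apart. Ugt3a2 (A/J minus AKR/J) was at 6.02 in liver and −0.06 in heart, 6.08 apart. Cyp2c39 (A/J minus C57BL/6J) was at 6.75 in liver and −0.03 in testis, 6.78 apart. The adjusted p of the interaction ran from 2.4e-62 for Nlrp12 to 1.44e-51 for Cyp2c39, and each value is a mean of 3 arrays per strain. The tissue pairs were those with the widest gap for each gene, picked from the data.

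The brain arrays 129S2 2 and AKR/J 2 were nearest to each other rather than to their own strains. An exchange of the 2 labels is excluded by the AKR/J share over marker genes. These were genes at least 1 log2 unit apart both averaged over the other tissues and, with the same sign, on the unaffected brain arrays. Over 32 such genes the share was 72.7% on the array labelled 129S2 2 and 39.6% on the one labelled AKR/J 2. It was −0.36% and 1.27% on the other 129S2 brain arrays (32 genes each) and 98.2% and 98.9% on the other AKR/J ones (33 and 30 genes). Animals that carry genes of both strains are excluded too, since the highest AKR/J share in the other tissues of 129S2 2 was 2.27% and the lowest in those of AKR/J 2 was 94.0%; the source name of the first array gives animal 129S2 1 instead, whose other tissues read 1.60% in heart and −2.52% in lung. RNA of both strains on each array is a candidate explanation: genes higher in AKR/J gave 72.2% and 41.4% on the 2 arrays and genes higher in 129S2 gave 73.4% and 37.6%, alike from gene sets that move in opposite directions. At which step samples could have been mixed was not tested.

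Clock genes of C57BL/6J stood in opposite order in 2 sets of tissues, with a score of 9 day genes minus 5 night genes that was +1.02 above the mean of the other strains in heart and lung and −1.55 in kidney and liver. In brain, from the same animals as heart and lung, it was not raised (−0.074, against +0.52 in A/J and −0.74 in DBA2/J). Alone, a strain difference of the clock shared by the tissues would give 1 sign, and the signs were opposite. The SD over the 3 C57BL/6J animals was at most 0.326 in heart, lung, kidney and liver. That SD lies within each set of animals, so a shared strain difference joined with a difference between the sets is not excluded. Different times of day at sampling for the 2 sets of C57BL/6J animals and a clock effect of C57BL/6J that depends on the tissue cannot be told apart, because 0 C57BL/6J animals were measured in both sets of tissues and sampling times are not given in the sources used here. The change of 2.57 between the sets, against at most 1.38 in size in another strain (129S2, whose animals also differ in part), is the pattern itself and favours neither.

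Among differences from C57BL/6J of at least 0.5, decreases outnumbered increases in each of the 5 strains over all genes, but not in AKR/J (47.1% decreases) or C3HeB/FeJ (49.6%) among genes with a mean log2 of at least 6, and at a difference of at least 1, the size taken for the probe sets, 28 of 56 genes in A/J and 41 of 80 in DBA2/J were decreases. The percentage of decreases moved by at most 2.52 points under a second quantile normalization and median centring. Both start from the deposited values, which were already normalized, so they cannot decide whether the authors' normalization is the source. Sequence differences from C57BL/6J under the probes cannot be told apart from lower transcript levels: another bright probe set bore out the decrease for 74.2% of genes lower by at least 1 (23 of 31) and the increase for 78.3% of genes higher by at least 1 (18 of 23; Fisher's exact test, p = 1). The other probe sets showed a median of 0.268 of the decrease and 0.619 of the increase, which goes the way of the probe explanation without settling it (permutation test, two-sided, p = 0.189), so these few genes leave it open. A biological difference in level between the strains stays untested as well.

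Other groupings of the same arrays were fitted in the same way, to see whether chance can be excluded. Within tissues, only the real grouping, 1 of 100 splits, gave as many genes: 4203 in brain (highest other split 159), 3824 in heart (18), 8389 in kidney (656), 5756 in liver (191), 5913 in lung (15) and 7371 in testis (799). For the tissue-averaged differences, animals were exchanged between a strain and C57BL/6J. Only the real grouping, 1 of 28, gave as many genes: 5395 in 129S2 (highest other 18), 5400 in A/J (6), 4850 in AKR/J (31), 5165 in C3HeB/FeJ (22) and 5371 in DBA2/J (4). For the interaction, animals were reassigned to strains, and only the real grouping, 1 of 100, gave as many genes, 13172 against at most 1622 in the others. Reassigning animals also breaks up the strain differences shared by the tissues. It therefore cannot exclude chance for the dependence on tissue by itself. For the counts within tissues and averaged over tissues, chance is excluded as far as these groupings go, and for the averaged counts they can give no share under 1 of 28.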

How the results depend on the processing

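The fits without brain arrays 129S2 2 and AKR/J 2, without C57BL/6J, without C57BL/6J and 129S2, and of the MHC class I list without 3 genes were chosen after the data were seen, as was leaving out each animal for families, lists and neighbours. The number of genes that differ, in each tissue, averaged and for the interaction, stayed within 1.5 times the reported count with a mean log2 of at least 6, the mean of probe sets, without probe sets ending in _x_at or _s_at, a second quantile normalization, median centring, and an intensity trend with a robust prior. The same held with array weights, run only within tissues, with no animal block or the animal number of the source name, run for the averaged counts and the interaction, and with only the arrays of the 2 strains, run for the averaged counts. It also stayed within 1.5 times without the 2 brain arrays (brain 5008, 129S2 5403, AKR/J 4760, interaction 13138), and the interaction without C57BL/6J (11751) and without C57BL/6J and 129S2 (10666). The number of arrays, 3 per group, limits precision, and so does signal over background: values depended on the filter on mean log2 for families, lists and tissue sharing.

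With every probe set by itself, a choice that tests more features, 7624, 6707, 14519, 9580, 11081 and 11533 probe sets differed in brain, heart, kidney, liver, lung and testis, 9767, 9775, 8710, 9247 and 9569 averaged in 129S2, A/J, AKR/J, C3HeB/FeJ and DBA2/J, and 22808 for the interaction. With a minimum difference, a stricter call by construction, 299, 649, 923, 1029, 948 and 744 genes remained in the same tissues, 390, 376, 333, 374 and 371 in the same strains and 5139 for the interaction. With a call on at least 2 probe sets of the same sign, which genes with a single probe set cannot meet, 1774, 1879, 1664, 1721 and 1776 were counted. With the replicate number as a block, 3724 genes differed in liver. The block left the counts of the other tissues within 1.5 times, at 3174 in brain, 2961 in heart, 6709 in kidney, 5213 in lung and 6010 in testis. No pairing of strains by number was assumed, and the cause of the fall in liver was not tested. Among genes with a mean log2 of at least 6 in every tissue, 93.3% passed in 1 or more tissues and 8.49% in all 6, and with that filter in the tissue 35 list tests passed rather than 53.

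Copy-number-variable families passed less often than other genes in brain, heart, kidney and testis over all genes, while in liver and lung the test did not pass. With both alternatives that allow for signal the difference was positive in all 6 tissues. With a mean log2 of at least 6 it was 8.14, 8.92, 12.9, 20.98, 18.2 and 6.66 points in brain, heart, kidney, liver, lung and testis, and against random lists matched on mean log2 it was 3.23, 5.84, 10.8, 9.48, 10.4 and 5.06 points. Both alternatives differ from the first test in the signal of the genes compared, by their construction. Without immunoglobulin and MHC genes the difference in lung was −7.88 points and passed (adjusted p = 0.00901); the cause was not tested. The heart call ended without DBA2/J heart 1 (−3.75 points, adjusted p = 0.137), without DBA2/J heart 2 (−4.46, 0.0687) and without C3HeB/FeJ heart 2 (−2.95, 0.301), and the kidney call without C57BL/6J kidney 12 (−5.55, 0.0812). With each array left out in turn, the difference ranged from −10.8 to −5.85 points in brain, −9.47 to −2.95 in heart, −9.88 to −5.55 in kidney, −1.35 to 1.38 in liver, −3.95 to 1.26 in lung and −15.4 to −11.8 in testis.

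With an estimated correlation 5 list shifts passed rather than 26. Neighbouring pairs with a difference of at least 1 numbered 1 in A/J (permutation p = 0.076) and 1 in DBA2/J (0.15), and without pairs that share symbol letters 7 in DBA2/J (0.061), fewer by construction. With the mean of its probe sets Xaf1 turned to +0.72 in 129S2 and +0.99 in DBA2/J, and H2-Q5 to +0.035 in C3HeB/FeJ, because their probe sets go apart. Cytochrome P450 genes in testis turned to +23.0 points with a mean log2 of at least 6; the cause was not tested.

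With each array or animal left out in turn, no count left 1.5 times the reported one and no neighbour call ended. The counts ranged from 3391 to 4762 in brain, 3054 to 4576 in heart, 7711 to 8237 in kidney, 5101 to 5716 in liver, 5136 to 6471 in lung and 6627 to 7269 in testis. Averaged over tissues they ranged from 4693 to 5508 in 129S2, 4473 to 5602 in A/J, 4113 to 5045 in AKR/J, 4441 to 5378 in C3HeB/FeJ and 4464 to 5554 in DBA2/J, and for the interaction from 12518 to 13221. List tests ranged from 44 to 56 and shifts from 23 to 34. Neighbour pairs ranged from 22 to 26, 21 to 24, 17 to 20, 25 to 33 and 17 to 22 in 129S2, A/J, AKR/J, C3HeB/FeJ and DBA2/J.

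Of single genes and lists named, 460 of 491 results stayed on their side of the threshold with a mean log2 of at least 6 (21 ended, 9 newly passed), 528 of 540 with the mean of probe sets, 524 of 525 without _x_at and _s_at probe sets, 534 and 537 of 540 under the 2 scalings, 536 of 540 with a trend, 303 of 303 with array weights and 224 of 227 with only the arrays of 2 strains. With the replicate block 284 of 303 did (17 ended, 2 newly passed), and with no block or the source name 237 of 237. With each array left out 290 of 313 did, and with each animal left out 243 of 253. The replicate block cannot judge the calls in kidney, liver and testis, where the C57BL/6J numbers occur in no other strain.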

Other observations

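The mean levels of some marker lists and stress-response genes not described above are given here as strain means of 3 arrays, with the highest and lowest strain and no test of the means themselves. By the list test, immediate-early genes in lung, neutrophil markers in heart, lymphocyte markers in lung, immunoglobulin genes in kidney and heat-shock genes in brain did not pass (adjusted p = 0.188, 0.444, 0.224, 0.517 and 0.0576), and 0 of 8 neutrophil markers passed singly in heart. Heat-shock genes averaged highest in AKR/J in brain (11.13), heart (11.33), kidney (12.08), liver (10.61) and lung (12.43), against lowest strain means of 10.55, 9.98, 10.98, 9.44 and 11.05. Immediate-early genes averaged 9.56 in A/J brain and 8.78 in 129S2 brain, and 10.83 in 129S2 lung and 9.68 in DBA2/J lung. Neutrophil markers averaged 5.66 in C3HeB/FeJ heart and 4.70 in DBA2/J heart, lymphocyte markers 8.28 in C57BL/6J lung and 7.66 in C3HeB/FeJ lung, and immunoglobulin genes 6.16 in C3HeB/FeJ kidney and 5.03 in AKR/J kidney. In liver, fatty acid synthesis genes averaged 10.34 in A/J and 9.54 in 129S2, while targets of PPAR alpha averaged 9.90 in 129S2 and 8.89 in AKR/J. Single members of the lists had wide ranges in tissues where they were not described above: Elovl3, a fatty acid elongase gene, ranged by 3.76 in liver with DBA2/J highest at 13.09 ± 0.127, the fibrinogen gene Fgg by 2.74 in kidney with C57BL/6J highest at 7.77, Hsd17b7 by 2.61 in heart with AKR/J highest at 8.80, Thrsp by 2.57 in testis with 129S2 highest at 7.01, and Lcn2 by 1.32 in lung.

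A few single arrays stood apart in markers of other tissues. Lung array C3HeB/FeJ 3 read 11.06 for skeletal muscle markers (next array 6.36), 9.03 for brown fat markers (next 6.87) and 11.95 for heart markers (next 10.76). Heart array C57BL/6J 3 read 7.91 for skeletal muscle markers (next 6.69), and testis array AKR/J 2 read 9.40 for smooth muscle markers (next 8.79).

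The search described here was chosen after the data were seen. In the 4 strains whose titles name the same animals in all tissues, 5 genes differed between 1 animal and the other 2 of its strain by at least 0.3 log2 units with the same sign in all 6 tissues, against a mean of 0.18 and a highest of 2 genes in 100 shuffles of the animal numbers within tissues. Fos (smallest difference 0.77, mean 1.5), Nr4a1 (0.30, mean 0.81) and Btg2 (0.35, mean 0.73), which are immediate-early genes, were higher in AKR/J 1, and Gbp2b (0.35, mean 0.57) and Gbp6 (0.31, mean 0.53), which are induced by interferon, were higher in A/J 2. Animals were also compared for genes known to vary in copy number. Glo1 was lowest in AKR/J 1 of the 3 AKR/J animals in heart, kidney, liver, lung and testis, with 9.42, 10.14 and 10.07 in testis and 11.32, 11.83 and 11.77 in lung for animals 1, 2 and 3. In brain, where array AKR/J 2 had an AKR/J share of 39.6%, animal 1 read 10.98 and animal 3 read 11.37, and the brain differences of Fos, Nr4a1 and Btg2 also take in that array. Ide was highest in C57BL/6J 12 of the 3 C57BL/6J animals of kidney, liver and testis, with 10.51, 10.59 and 10.94 in kidney, 10.51, 10.38 and 10.87 in liver and 11.73, 11.73 and 12.06 in testis for animals 10, 11 and 12. In the C57BL/6J animals of brain it read 9.15, 9.27 and 9.20.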
